A study of Mus musculus with 13 samples.

How the data were processed

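Poly(A)-selected RNA-seq of primary mouse bone marrow neutrophils was held for 2 mock and 2 exRNaseA libraries, and small RNA sequencing for 9 groups of 1 library each: HOXB8 input, biotin and WGA, differentiated HOXB8 input, biotin, WGA and biotin with PNGase F, and neutrophil input and WGA. HOXB8 cells were grown with 1 µM estradiol and 100 ng/ml SCF and labelled for 36 h with 100 µM Ac4ManNAz, a precursor of azide-bearing sialic acid, with 10 µM Gal and 100 µM GalNAc, per the labels' protocols. The RNase A text stands in the labels of the mock libraries too, so the groups were taken from the treatment field.

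The deposited expected counts were made by the authors with STAR 2.4.2a and RSEM 1.3.3 on mm10, per the submitters' processing notes. The deposited TPM and FPKM values come from the same RSEM output, per the file headers. Strand setting and annotation release were not given in the sources used here. The deposited small RNA values are RPM, reads of each unique sequence scaled to the library's reads. Every value was a whole multiple of 1 read within 0.01, so whole reads were recovered. The aligner, the trimming and the filter behind the small RNA table were not given in the sources used here, and the labels name mm10. The small RNA table is titled non-miRNA, so its miRNA class may hold only a part of the miRNA reads. The table left out part of each library, so shares are of the summed RPM in the table, while RPM refers to the whole library.

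Of 55536 genes 55450 had a symbol, and the RefSeq table (GRCm38.p6, which is mm10) gave a biotype to 90.8% of tested genes. Expected counts were rounded to whole numbers. edgeR's filterByExpr left 14184 genes, TMM scaled the libraries (factors 0.993 to 1.01), and the quasi-likelihood F test compared the groups with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.0244. A 95% interval of each log2 change came from the test's F value, and 10 standard errors came from limma-voom where F was near 0. A gene at 0 in a group was set against a floor of 3 counts per group.

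The 26 gene lists were fixed before the data were examined, as were the groups, the tests, the first set of alternatives and the naming rule. They cover neutrophil maturation and secondary granules, primary granules, adhesion, NF-κB and cytokines, immediate early and stress genes, interferon response, nucleic acid sensing, Sidt RNA transport, sialylation and N-glycans, siglecs and other lectin receptors, nucleases and RNase inhibitors, ribosomal proteins, mitochondrially encoded mRNAs, apoptosis, cell cycle, surface RNA-binding proteins, nuclear lncRNAs and markers of 9 other kinds of cell. The camera test of limma (preset correlation 0.01) ran on the 24 lists with 5 or more tested members, with Benjamini-Hochberg adjustment over lists.

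The rule named up to 15 genes per direction with the largest change among called genes with both exRNaseA libraries on the same side of both mock libraries. If fewer than 5 passed, the 5 with the smallest unadjusted p were named. It also named the 3 most abundant members of each list and the member with the smallest p, and Sidt1, Sidt2 and Rnh1. In small RNA it named every class at 5% or more of a library, the 3 highest sequences of each purified library, the 3 with the largest ratio to input among those at 100 RPM or more, and the Y RNA, vault, 7SK and 7SL sums. Akap2, Ly6g, Ltf, Lyz2, Camp, Cxcr2, Hspa1a, the PNGase contrasts of single sequences and the sequences called by limma were named after their values were seen. Some genes that the rule names are not reported here.

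Small RNA shares have exact Clopper-Pearson 95% intervals and read ratios exact conditional intervals, both of counting error only. The 3 WGA to input ratios of a class were tested with an exact sign-flip permutation test. Sequences were tested over the 3 kinds of cell with limma (trend, kind of cell as block) on log2(RPM + 1).

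The fits were tested on simulated data. For edgeR on 2 and 2 libraries, 32 of 50 genes changed 1.5-fold were called, 40 of 50 at 2-fold, 45 of 50 at 4-fold and 50 of 50 at 8-fold, with 11 false calls among 13768 unchanged genes. Intervals covered the true value for 95.5% of 13965 genes. For limma over the 3 kinds of cell, 3 noise models were simulated, with 50 changed sequences at each of 4, 16, 256 and 1024-fold. With a variance that follows the mean, 1, 0, 35 and 48 were called, with 0 false calls among 17706. With the same log2 SD for all sequences, set to 1.87 as the median of the real fit, 0, 2, 34 and 50 were called. There were 0 false calls among 17698. With negative binomial counts and the same dispersion for all sequences, 0 were called at every fold, with 0 false calls among 17201.

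The alternatives were DESeq2, total count and upper quartile scaling, no filter, a stricter filter (10 CPM in 2 libraries), limma on log2 TPM and FPKM, the replicate number as a block, each library left out, a threshold of 0.1, another prior count (0.5), estimated correlation and fry for lists, and for small RNA other pseudocounts (10 and 0.1), median-ratio scaling, a filter at the median mean, no block, each kind of cell left out, each library's 10 highest sequences left out and shares of distinct sequences. Added after seeing the data were fits without the 5 rRNA-sequence genes, edgeR on recovered reads, sequences of 20 or more bases, and class shares of all reads of each library. The replicate numbers of the RNA-seq groups are not said to mark a shared animal or day. Versions were edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, R 4.3.3, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.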

Results

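RNA of mouse cells was sequenced in 2 ways. Poly(A)-selected RNA-seq covered primary bone marrow neutrophils given a mock treatment (mock, n = 2 libraries) or RNase A added outside the cells in buffer for 10 min at 37 °C (exRNaseA, n = 2 libraries). The mock libraries held 23722494 and 20798960 expected counts and the exRNaseA libraries 20661683 and 22870322. Small RNA sequencing covered 9 groups with 1 library each. The cells were HOXB8 cells, a myeloid progenitor line held undifferentiated by estradiol, HOXB8 cells differentiated by removing estradiol, and primary neutrophils. RNA was sequenced as a gel-purified input of under 300 nt, after streptavidin capture of biotin that had been clicked onto metabolically labelled sialic acid, after capture on wheat germ agglutinin (WGA) beads, or, in differentiated cells, after biotin capture and digestion with PNGase F, an enzyme that releases N-glycans. The 9 small RNA libraries held between 3110323 and 9922659 reads each, of which between 39.3% and 96.7% were in the table. The series calls the RNA-seq libraries biological replicates. Nothing used here says that they came from separate animals, so their p-values measure the spread between these 4 samples.

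The RNA-seq comparison asked whether RNase A outside intact neutrophils changes the RNA inside them. The neutrophil messages stayed close to their mock level, and the called genes that differed by over 2-fold at a mean of 10 CPM (counts scaled to library size) or more were 5 genes that carry ribosomal RNA (rRNA) sequence. Lars2 (ENSMUSG00000035202.8, chromosome 9, 123366927 to 123462675, mm10), a gene of a mitochondrial leucyl-tRNA synthetase, fell from 1915 ± 337 to 78.5 ± 2.11 CPM (mean ± SD, n = 2 per group), a log2 change of -4.61 (SE 0.08). Gm26917 (ENSMUSG00000097971.3) fell from 458 ± 77.5 to 10.6 ± 1.07 CPM, Gm42418 from 358 ± 72.7 to 70.9 ± 3.14, AY036118 from 873 ± 89 to 219 ± 22.7, and CT010467.1 from 3484 ± 361 to 1091 ± 75. Their log2 changes were -5.42, -2.33, -1.99 and -1.67. Together these 5 genes held 7088 CPM in the mock and 1470 CPM in the exRNaseA libraries, 4.82-fold lower. The deposited counts of Gm42418, AY036118 and CT010467.1 were not whole in any of the 4 libraries, so reads were shared between genes there, while those of Lars2 and Gm26917 were whole in all 4. Whether reads counted to these genes came from rRNA itself cannot be read from the counts. The 5 genes were grouped as carriers of rRNA sequence from general knowledge, after their values were seen.

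edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 13 of 14184 tested genes, 10 lower and 3 higher. The adjusted p was 3.93e-18 for Lars2, 1.10e-17 for Gm26917, 1.02e-12 for Gm42418 and 6.29e-15 for AY036118 and for CT010467.1. DESeq2 called 9 genes, 7 of them shared, and every alternative that tested the 5 rRNA-sequence genes called them in the same direction. Without the 5 genes, an alternative chosen after seeing the data, 3 calls were left.

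**Figure D1:**
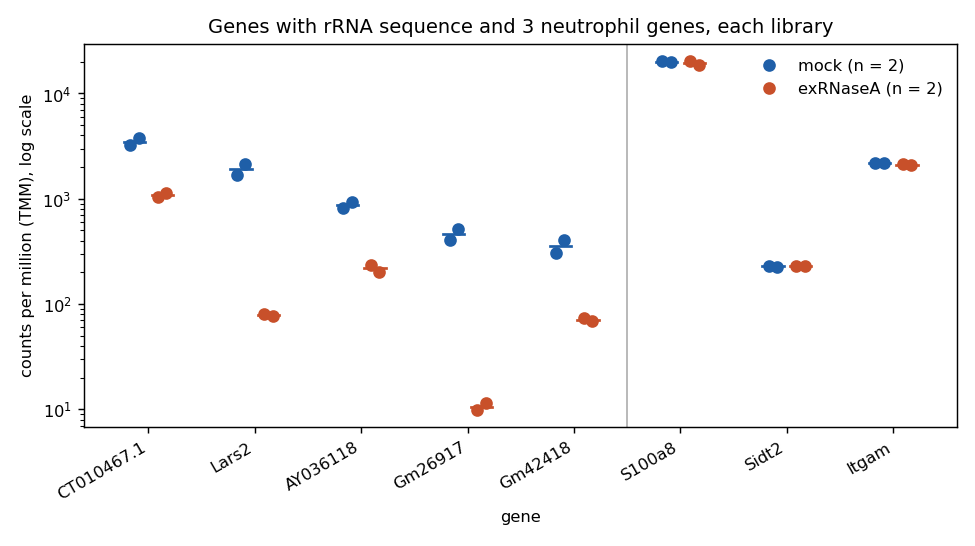
CPM (TMM scaled, log axis) of the 5 genes with rRNA sequence and of S100a8, Sidt2 and Itgam. Each point is a library and each short line the mean of a group (n = 2); Lars2 means were 1915 in mock and 78.5 in exRNaseA, S100a8 means 20110 and 19450.

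The other called genes were weakly expressed or changed little. Gm18852, a transcribed pseudogene on chromosome 7 (105924344 to 105928691, mm10), had 43 and 23 counts in the mock libraries and 0 in both exRNaseA libraries, at least 21.5-fold lower against a floor of 3 counts per group (adjusted p = 0.000696, edgeR). Hist2h3c1, a histone H3 gene, had 17 and 12 counts against 0 and 0, at least 9.45-fold lower (adjusted p = 0.0343, edgeR). Pakap had 46 and 30 counts against 0 and 1, a mock to exRNaseA ratio of 75.3 (95% exact interval 13.1 to 3011, counting error only; adjusted p = 0.000307, edgeR). Pakap overlaps Akap2, whose counts were 83 and 79 in the mock and 133 and 128 in the exRNaseA libraries, so reads of these overlapping genes cannot be told apart here. Gm13237 fell by 0.93 and Gm29216 by 0.22 on the log2 scale (edgeR adjusted p = 0.0343 and 0.00189). Gm6793 rose by 1.23, Ube2n-ps1 by 0.75 and Cdk6, a cell cycle kinase, by 0.21 (edgeR adjusted p = 0.0483, 0.0343 and 0.0343). Histone genes and pseudogenes have near-identical copies, and 10 of the 13 called genes had expected counts that were not whole in some library, so these calls are uncertain. DESeq2 did not call Cdk6, Pakap, Gm6793, Hist2h3c1, Gm13237 or Ube2n-ps1, limma on TPM or FPKM did not call Cdk6, Gm6793, Gm13237, Ube2n-ps1 or Gm29216, and leaving out a library ended calls among Cdk6, Gm6793, Hist2h3c1, Gm13237, Gm29216 and Ube2n-ps1. Gm18852, Hist2h3c1 and Pakap lay under the minimum for TPM and FPKM and were not tested there. The upward set was filled to 5 by the naming rule with AC129217.1 (log2 change 1.67, adjusted p = 0.0792) and Slc16a6 (0.19, adjusted p = 0.201), which did not pass the edgeR test.

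**Figure D2:**
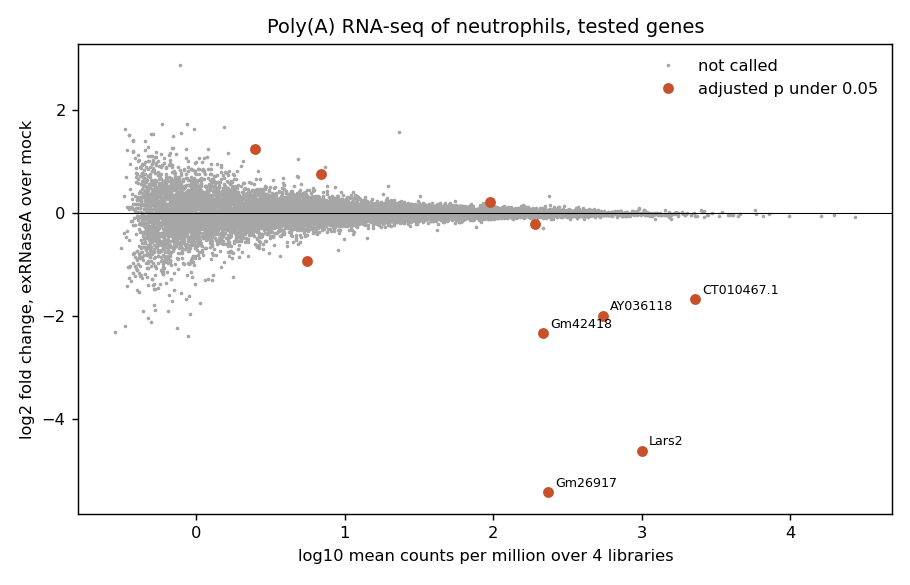
Log2 fold change (exRNaseA over mock, edgeR) of each tested gene against its log10 mean CPM over the 4 libraries, with called genes as large points. Genes with 3 or fewer counts in a group are not drawn, among them Gm18852, Hist2h3c1 and Pakap; the largest fall drawn is Gm26917, at -5.42.

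Most genes could be bounded. The 95% interval of the log2 change lay within ±1 for 85.3% of tested genes and for 99.9% of the 7828 genes at a mean of 10 CPM or more; 99.5% of the latter lay within ±0.5. The median absolute log2 change was 0.07. The share within ±1 was 50.1% without the expression filter, which moves it by over 1.5 times. Correlations of log2 CPM across genes, which are not independent replicates, were 0.992 within groups and 0.992 between groups on average, and the between-group distance was 1.02 times the within-group distance. The log2 change had a Spearman correlation of 0.06 with transcript length across genes, against 0.05 for each pair of replicates. Protein-coding genes had a median log2 change of -0.00 over 11613 genes, lncRNAs 0.02 over 597 and mitochondrially encoded genes -0.02 over 15.

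Genes linked to RNA handling at the cell surface did not pass the test. Sidt2, a member of a family of RNA transport proteins, had 227 ± 3.03 CPM in mock and 231 ± 0.57 in exRNaseA libraries (log2 change 0.03, adjusted p = 0.936, edgeR). Sidt1 had 5.13 ± 0.07 and 4.86 ± 0.20 CPM (-0.08, adjusted p = 0.959, edgeR). Rnh1, the cytosolic inhibitor of RNase A, had 23.7 ± 1.68 and 23.8 ± 1.5 CPM (0.00, adjusted p = 0.999, edgeR). Of 42 tested genes of sialylation and N-glycan synthesis 0 were called (median log2 change -0.02; St6gal1 -0.16, St3gal5 -0.05). Of 19 genes of RNA-binding proteins reported at cell surfaces 0 were called (median 0.00; Ddx3x -0.02, Hnrnpa2b1 0.00). Of 18 siglec and lectin receptor genes 0 were called (median -0.02; Cd33 0.00), and of 20 nuclease and RNase inhibitor genes 0 (median -0.05; Xrn1 -0.02, Rnaset2b -0.03).

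Of 36 granule and maturation genes 31 had a negative log2 change, with a median of -0.05. S100a8 had 20130 and 20090 CPM in the mock libraries and 20170 and 18730 in the exRNaseA libraries, which overlap (adjusted p = 0.762, edgeR). S100a9 had 28190 ± 109 CPM in mock and 26620 ± 1198 in exRNaseA libraries (log2 change -0.08), Ngp -0.05 and Itgam -0.05. Over all genes 0 were called, and adjusted over the list alone 7 were: S100a9, Ly6g, Ltf, Lyz2, Ngp, Camp and Cxcr2. The camera test of limma with a preset correlation gave this list an adjusted p = 0.0355, and an adjusted p = 0.676 with an estimated correlation. The camera test of limma also called the interferon response list (35 genes, 23 negative, median -0.03, adjusted p = 0.0482; Ifitm3 -0.10) and the eosinophil, basophil and mast cell markers (15 genes, 12 negative, median -0.09, adjusted p = 0.0482; Prg2 -0.07, Mcpt8 -0.73). For both of these the adjusted p = 0.676 with an estimated correlation, and 0 members were called over all genes or adjusted over the list alone. The 3 list calls were also lost with fry, under total count scaling and when any library was left out.

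The other 21 lists tested were not called by camera, and 0 of their members were called over all genes. Among stress and activation lists, immediate early and heat shock genes (38 tested) had a median of -0.01, NF-κB and cytokine genes (30 tested) -0.04, apoptosis and survival genes (28 tested) -0.04, and nucleic acid sensors (22 tested) -0.01. Atf3 (-0.18) and Hspa1a (0.51) of the immediate early list, Neat1 (0.09) of the nuclear lncRNAs (13 tested, median 0.03) and Ermap (0.11) of the erythroid markers (14 tested, median 0.04) passed when adjusted over the list alone. Primary granule genes (15 tested) had a median of -0.00, adhesion genes (26 tested) -0.01, cell cycle genes (33 tested) 0.02, ribosomal protein genes (74 tested) 0.00 and mitochondrially encoded mRNAs (13 tested) 0.00. Markers of other cells had medians of 0.00 for B cells (14 tested), -0.08 for T and NK cells (15), 0.02 for monocytes and macrophages (14), -0.03 for dendritic cells (10), -0.09 for megakaryocytes (8) and 0.02 for stem and progenitor cells (10). Among the markers, Ighm stood at 1368 ± 1.06 CPM in mock and 1332 ± 6.13 in exRNaseA libraries, Hbb-bs at 519 ± 12 and 510 ± 8.46, and Ly6c2 at 418 ± 4.08 and 404 ± 6.44. The stromal markers (4 tested genes, median 0.03) and Sidt genes (2 tested) were too few for camera. The most abundant members of the lists, 76 genes in all, had log2 changes between -0.20 and 0.20, and 0 of them were called (lowest adjusted p = 0.288, edgeR).

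The small RNA comparisons asked which RNA classes and fragments were carried by the glycan-directed purifications. The labels give the cut of under 300 nt for the inputs only. Ratios to input therefore cannot tell capture from a difference in size selection. With 1 library per group these differences have no replicate check, and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. In HOXB8 cells, WGA capture went with a genome-mapped share of 35.6% of the table (exact 95% interval 35.5 to 35.6) against 7.47% in the input, and with snoRNA at 0.551% against 5.70%. In differentiated HOXB8 cells the genome share was 34.1% after WGA and 3.48% in the input, and snoRNA 1.00% and 11.1%. In neutrophils rRNA fragments held 80.1% after WGA and 76.4% in the input, tRNA fragments 8.79% and 3.37%, snoRNA 4.03% and 7.54%, and the genome class 1.68% and 2.25%. ncRNA stood at 6.26% and 11.1% in HOXB8, 3.99% and 11.2% in differentiated and 1.94% and 3.06% in neutrophil WGA and input libraries.

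**Figure D3:**
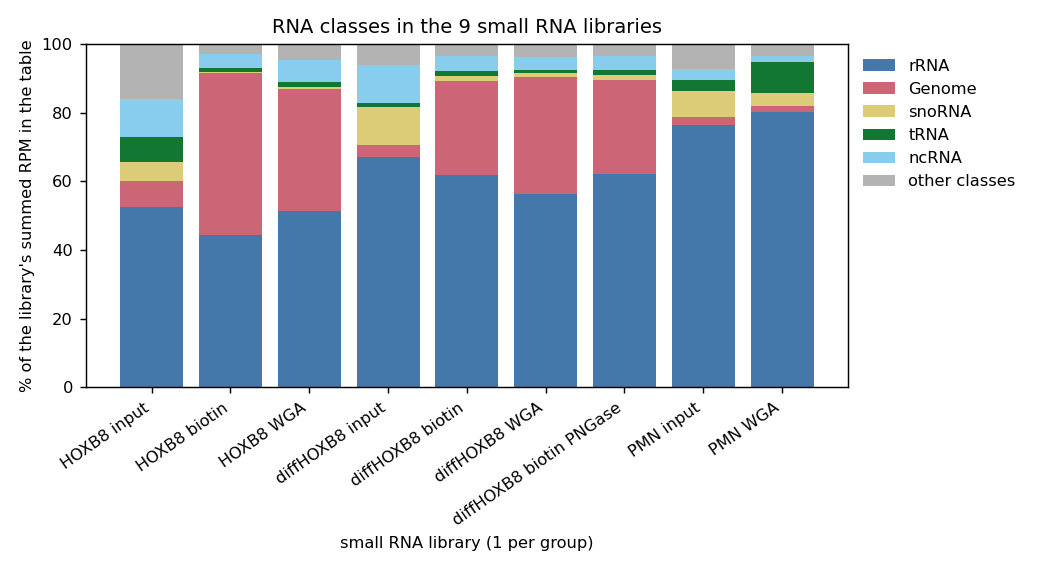
Share of each small RNA library's summed RPM (reads scaled to library size) in the table, by RNA class as the table annotates it (1 library per bar). The genome class holds 47.1% of the HOXB8 biotin library and 1.68% of the neutrophil WGA library.

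On the log2 scale the WGA to input ratio of the genome share was 2.25 in HOXB8, 3.29 in differentiated HOXB8 and -0.42 in neutrophils. For tRNA it was -2.31, -0.44 and 1.38, for rRNA -0.03, -0.25 and 0.07, and for snoRNA -3.37, -3.47 and -0.90. As shares of the table's value, the classes 7SL, miRNA, ncRNA, pre-miRNA, snRNA and snoRNA were lower after WGA in all 3 kinds of cell. Because the table is titled non-miRNA, its miRNA class may not stand for the miRNA of these libraries. The exact two-sided sign-flip permutation test on 3 pairs cannot go below p = 0.25, which each of these 6 classes reached. Alternatives were run for the genome, ncRNA, rRNA, snoRNA and tRNA classes. Without each library's 10 highest sequences ncRNA was higher after WGA, at 0.09, 0.09 and 0.53 in HOXB8, differentiated and neutrophil cells. As a share of distinct sequences snoRNA was higher in HOXB8 (0.12) and differentiated cells (0.28) and lower in neutrophils (-0.85), and tRNA was lower in neutrophils (-0.67). The rRNA ratios were 0.51, -0.21 and -0.19 without the 10 highest sequences and 0.32, 0.28 and 0.18 at 20 or more bases. The genome direction turned in HOXB8 cells and neutrophils, but not in differentiated cells, in 3 alternatives. Among sequences of 20 or more bases, a cutoff chosen after seeing the data, the ratios were -0.76, 1.09 and 2.07. Without each library's 10 highest sequences they were -0.16, 1.63 and 0.77, and as shares of distinct sequences -0.19, 0.77 and 0.42.

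The table held 39.3% of the reads of the HOXB8 input and 90.6% after WGA, so shares of the table and shares of all reads of the library differ. As shares of all reads, an alternative chosen after seeing the data, the WGA to input log2 ratios of rRNA were 1.17, 0.21 and 0.10 in HOXB8, differentiated and neutrophil cells, higher in all 3. The ncRNA ratios were 0.38, -1.03 and -0.64 and the miRNA ratios 0.79, 0.21 and -1.27. For tRNA they were -1.11, 0.02 and 1.41, for snoRNA -2.17, -3.01 and -0.88, and for the genome class 3.46, 3.76 and -0.39. Of the 6 classes lower in all 3 kinds as shares of the table, 7SL, pre-miRNA, snRNA and snoRNA were also lower in all 3 as shares of all reads, with differentiated pre-miRNA at -0.01. Summed miRNA stood at 13589 and 23564 RPM in HOXB8 input and WGA libraries, and summed rRNA at 206682 and 465951 RPM.

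After biotin capture the genome share was 47.1% in HOXB8 and 27.4% in differentiated biotin libraries, snoRNA 0.441% and 1.51%, tRNA 1.04% and 1.46%, rRNA 44.4% and 61.9%, and ncRNA 4.05% and 4.25%. Of 515 HOXB8 sequences at a mean of 100 RPM (reads scaled to library size) or more, 74.2% lay within 2-fold between WGA and biotin; in differentiated cells it was 69.8% of 311. Across sequences, which are not independent replicates, biotin and WGA libraries had a Pearson r of 0.680 in HOXB8 and 0.412 in differentiated cells. The differentiated tRNA share had a log2 ratio to input of 0.31 after biotin and -0.44 after WGA. The biotin to input log2 ratio of the genome share was 2.66 and 2.98. Without each library's 10 highest sequences it was -0.28 and 0.85, and among sequences of 20 or more bases -1.31 and -0.64.

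A pair of short sequences made up between 86.9% and 92.2% of the genome class in the purified HOXB8 libraries, differentiated ones included. AGCGGAGTAGAGCAGT (chromosome 7, 81731500 to 81731515, mm10, reverse strand) stood at 7200 RPM in the HOXB8 input, 306900 after biotin (42.6-fold higher, 42.1 to 43.1) and 193200 after WGA (26.8-fold). In differentiated cells it stood at 6041 RPM in the input, 192300 after biotin and 252600 after WGA, and in neutrophils at 10280 in the input and 755 after WGA. TTAAGTAAGAGTATTTGG (chromosome X, 142215582 to 142215599, reverse strand) stood at 1410, 92450 and 86840 RPM in HOXB8 input, biotin and WGA libraries and at 2018 and 156.7 RPM in neutrophil input and WGA libraries. Reads of 16 and 18 bases can match more places than the table lists, so the position is uncertain. Together the pair took 43.5% of the HOXB8 biotin library, 30.9% of the HOXB8 WGA library and 0.101% of the neutrophil WGA library. Without them the WGA to input log2 ratios of the genome share were 0.32, 1.11 and 0.86 in HOXB8, differentiated HOXB8 and neutrophils, so the neutrophil value turned direction.

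The table gives positions on a 45S record but not its parts, so spacer, 18S, 5.8S, 28S and 5S pieces were assigned from general knowledge and not checked by sequence. A fragment from the 5′ external transcribed spacer, a part of the 45S rRNA precursor that is removed during ribosome synthesis, was higher in every purified library than in its input. The sequence TCTTAGATCGATGTGGTGCTC (positions 652 to 672 of the 45S record) stood at 26750 RPM in the HOXB8 input against 114400 after WGA (4.28-fold, 4.25 to 4.31) and 117700 after biotin (4.4-fold). It stood at 18130 in the differentiated input against 99820 after WGA (5.51-fold) and 86570 after biotin (4.78-fold). In neutrophils it stood at 10290 in the input and 183300 after WGA (17.8-fold, 17.6 to 18.0), and CTCTTAGATCGATGTGGTGCTC, 1 base longer, at 2639 and 73540 (27.9-fold). The first 1000 positions of the record held 8.20%, 15.6% and 15.1% of the HOXB8 input, biotin and WGA tables, 3.70%, 13.7% and 14.9% in differentiated cells, and 1.59% and 29.8% in neutrophil input and WGA libraries.

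**Figure D4:**
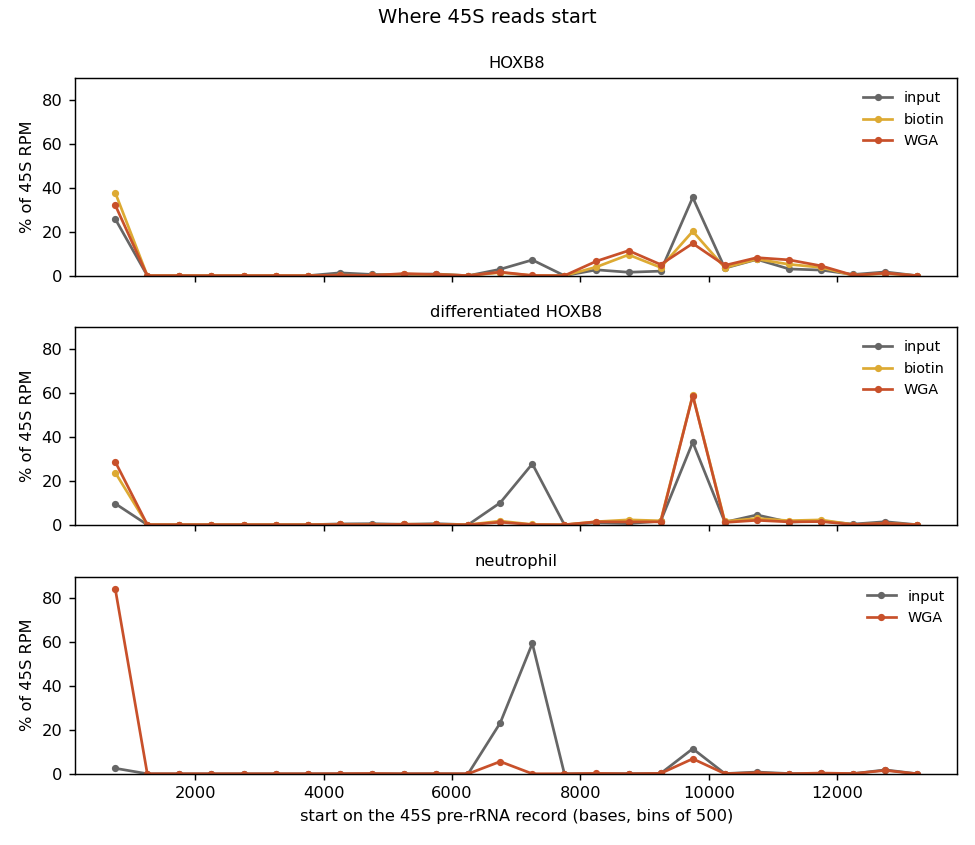
Share of the 45S value (%) by read start in bins of 500 bases along the 45S record, in input, biotin and WGA libraries of the 3 kinds of cell (1 library per line). In neutrophils the bin from 501 holds 84.5% after WGA and 2.51% in the input, and the bin from 7001 holds 0.0113% and 59.5%.

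Inside the 28S part of the precursor, GATATAGACAGCAGGACGGTGGCCA (positions 9879 to 9903) stood at 1198 RPM in the differentiated input, 214600 after biotin (179-fold, 174 to 184) and 196600 after WGA (164-fold). The shorter GATAGACAGCAGGACGGTGGCCA, listed at positions 9881 to 9903, differs in its first base from the longer sequence at that place. It stood at 36.2, 19930 and 29060 RPM in the same libraries, the largest WGA ratio of that cell with 1 RPM added to both values (802-fold without it, 679 to 955). In HOXB8 cells the longer form stood at 893.8, 44260 and 33750 RPM, and in neutrophils it was lower after WGA, at 1472 and 176.4 RPM. With 1 RPM added, the largest HOXB8 ratios belonged to G-rich 45S fragments. GGGAAGGTGGCTCGGGGGGG had 0 reads in the HOXB8 input and 1484 RPM after WGA, at least 1850-fold higher against a floor of 3 reads, and 1259 RPM after biotin, at least 1570-fold. GCGGCGGGCGCGGGGGG was 1106-fold higher after WGA (508 to 3015) and GGTGAGGCGGGGGGGCG 1050-fold (482 to 2861), each on 6 input reads. GGTCCGGAGCGGGAGG, with 1 input read, had a biotin ratio of 1641 (294 to 64820). CGAGGTGCGTGGGGGGG had 0 reads in the differentiated input and 311.5 RPM after WGA, at least 395-fold higher. The genome sequence TGGCTCAGTTCAGGAAC (chromosome 2) had 1 differentiated input read and 400.6 RPM after WGA, a ratio of 1526 (274 to 60290).

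The 5.8S region showed the opposite. Reads that start at positions 6501 to 7500 of the 45S record, a window around 5.8S rRNA and wider than it, held 3.21% of the HOXB8 input and 0.824% after WGA, 14.5% and 0.631% in differentiated cells, and 52.3% and 1.97% in neutrophils. A 5S and an 18S piece of mature rRNA, named for their neutrophil WGA values, were higher there than in the input. Both were also higher in biotin RNA of both HOXB8 kinds. In neutrophils the 5S piece, of 95 bases, stood at 1854 RPM in the input and 135600 after WGA (73.1-fold, 71.3 to 75.1). The 18S piece, longer and from the 5′ end, stood at 45 and 22150 (492-fold, 417 to 585). In differentiated cells the 5S piece stood at 91.1 RPM in the input, 5135 after biotin and 476 after WGA, and the 18S piece at 3.94, 188.1 and 2.23. In HOXB8 cells they stood at 147, 814 and 166 RPM and at 3.2, 30.6 and 1.99 RPM. In neutrophils a 71-base rRNA piece had 0 input reads and 350.2 RPM after WGA, at least 363-fold higher. The mean read length was 39.1 bases in the neutrophil WGA library and between 19.7 and 29.2 in the other 8.

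Over the 3 kinds of cell, limma on log2(RPM + 1) with kind of cell as a block called 419 of 17923 sequences between WGA and input, 410 lower and 9 higher. snoRNA and 5.8S pieces led the lower calls. The snoRNA sequence GAACGCAGTCTGAGTGGA stood at 1665, 5871 and 3155 RPM in the inputs of HOXB8, differentiated and neutrophil cells and at 0.181, 0.351 and 0 RPM after WGA (adjusted p = 3.06e-14, limma). The 5.8S piece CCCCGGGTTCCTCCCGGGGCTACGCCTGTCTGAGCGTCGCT stood at 196.5, 2218 and 11780 RPM in the inputs and 0, 0.234 and 0.806 RPM after WGA (adjusted p = 3.24e-12, limma). The lower calls were 222 rRNA, 66 snoRNA, 39 ncRNA, 32 genome, 15 snRNA, 10 tRNA, 9 miRNA, 8 pre-miRNA, 5 precursor RNA, 3 sRNA and 1 antisense RNA sequences. Among the 17923 tested sequences 9566 were rRNA and 546 snoRNA. The rRNA count thus lay near its share of those tested, and the snoRNA count above its share. Of the 9 higher calls, 5 were higher in all 3 kinds of cell, among them ATTCGGCTGATCTGGC, an snRNA piece (2.4, 2.36 and 2.25 RPM in the inputs, 65.6, 187 and 101.1 after WGA), and 4 were lower in neutrophils. The spread in this test is that between kinds of cell, not between replicates of any. The count was 23 without the differentiated pair, 147 without the HOXB8 pair and 27 with edgeR on recovered reads, with 0 higher in each, and 1871 without the neutrophil pair, 769 of them higher.

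Per purified library, between 1740 and 6533 sequences were 4-fold or more higher than in the input and between 1914 and 4490 were 4-fold or more lower, with 1 RPM added. The counts were 6533 higher and 3242 lower for HOXB8 WGA, 5604 and 3217 for HOXB8 biotin, 4425 and 4490 for differentiated WGA, 5142 and 3822 for differentiated biotin, 4889 and 3790 after PNGase, and 1740 and 1914 for neutrophil WGA. In all 3 WGA libraries 73 sequences were 4-fold or more higher and 874 were 4-fold or more lower. Of the 73, 38 were rRNA, near the rRNA share of the table (9798 of 18385 sequences). In the named RNAs, 7SL sequences summed to 2151, 735 and 1059 RPM in HOXB8 input, biotin and WGA libraries, 1606, 929 and 1009 in the differentiated ones, and 1357 and 498 in neutrophil input and WGA libraries. The 1 Y RNA sequence had 84 reads in the differentiated biotin library and 0 in every other purified library. It had 13, 14 and 1 reads in HOXB8, differentiated and neutrophil inputs. Names with 7SK in capitals or with vault matched 0 sequences, and other spellings of 7SK were not searched. The search was by name and not by sequence, so it does not show that 7SK was absent. The snRNA pieces named here were not checked for 7SK sequence. With 10 RPM added the counts of higher sequences lay between 346 and 1536.

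The PNGase F comparison asks whether the fragments of a digested biotin sample differ from those of an undigested one. The sample's title does not say which fraction of the digest was sequenced. The digested and undigested biotin libraries of differentiated HOXB8 cells had class shares close to each other. The genome share was 27.4% in both, rRNA 62.2% against 61.9%, snoRNA 1.43% against 1.51% and tRNA 1.37% against 1.46%. Of 350 sequences at a mean of 100 RPM or more, 94.3% lay within 2-fold, 6 were 4-fold or more higher after digestion and 6 were 4-fold or more lower. Across all sequences, which are not independent replicates, the Pearson r of this pair was 0.702 and the Spearman correlation 0.614. The spacer fragment TCTTAGATCGATGTGGTGCTC stood at 96850 RPM after digestion and 86570 before. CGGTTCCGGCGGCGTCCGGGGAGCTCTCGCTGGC, a 45S fragment, stood at 0.465 RPM after digestion and 712.1 before, and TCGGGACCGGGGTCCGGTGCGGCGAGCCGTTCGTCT, annotated as miRNA, at 0.310 and 346.1. The latter stood at 0.643 RPM or less in every other library, undigested ones included. The 45S fragment stood at 139.9 RPM in HOXB8 biotin, 98.98 in differentiated WGA and 1.087 in HOXB8 WGA libraries. With 1 library each, these falls cannot be told from a difference between libraries. ATCCGGGTGCCCCCTCCA, a tRNA piece, stood at 529.7 RPM after digestion, 473.7 before and 0.788 in the input (3 reads), a ratio of 673 to the input (230 to 3263). These are relative values: a digestion that removed all captured RNA alike would leave them equal.

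Differentiation went with a different input profile. The rRNA share was 67.0% in the differentiated and 52.6% in the undifferentiated HOXB8 input, snoRNA 11.1% and 5.70%, tRNA 1.18% and 7.18%, genome 3.48% and 7.47%, and ncRNA 11.2% and 11.1%. The HOXB8 input had 39.3% of its reads in the table, against 70.2% in the differentiated input and 88.3% in the neutrophil input, so RPM and share ratios differ between these libraries. Summed in RPM, differentiated and undifferentiated inputs held 470281 and 206682 of rRNA, 78181 and 22394 of snoRNA, 78684 and 43601 of ncRNA, 8275 and 28224 of tRNA, and 24394 and 29350 of the genome class. After biotin capture the log2 ratio of the genome share, differentiated over undifferentiated, was -0.78, with rRNA at 61.9% against 44.4%. The genome ratio turned to 0.46 without each library's 10 highest sequences and to 0.0611 as distinct sequences. It stayed negative at the median mean (-0.79), at 20 or more bases (-0.61) and as a share of all reads (-0.76). After WGA the genome shares were 34.1% and 35.6%, and their log2 ratio was 1.13 without the 10 highest. Against the differentiated line, neutrophils had a tRNA share of 3.37% against 1.18% and an ncRNA share of 3.06% against 11.2% in the input, and after WGA a tRNA share of 8.79% against 0.869%, snoRNA of 4.03% against 1.00% and genome of 1.68% against 34.1%. The labels give the metabolic labelling step in the same words for all small RNA samples, so whether the neutrophils were labelled is unknown.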

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

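The tests of read length and of bead shedding were chosen only after the result was seen. Leaving out each library's 10 highest sequences was fixed before the data were examined. Its use to explain this result was chosen afterwards. The genome class differed in direction between kinds of cell: the log2 ratio of its share, WGA over input, was -0.42 in neutrophils, against 2.25 in HOXB8 and 3.29 in differentiated HOXB8 cells. The difference was not tested, with 1 library per group. Sequences shed by the WGA beads are argued against by the biotin libraries, which used other beads and whose genome share lay at a log2 ratio of -0.31 or more to the WGA libraries. Among sequences of 20 or more bases the ratio turned to 2.07 in neutrophils and -0.76 in HOXB8 cells, and without each library's 10 highest sequences to 0.77 and -0.16. The latter left out each library's own 10 highest, so a sequence left out after WGA could stay in the input. Leaving the pair of leading short genome sequences out of both libraries gave 0.32 in HOXB8 cells and 0.86 in neutrophils. Short reads may therefore set the direction in these cells, and a few abundant sequences in neutrophils. In neutrophils these are not separate accounts. Both sequences of the pair are under 20 bases long, and together they held 61.8% of the genome class in the neutrophil input. For HOXB8 cells the values on abundant sequences differ and cannot decide. In differentiated HOXB8 cells the ratio stayed above 0, at 1.09 and 1.63. Neither short reads nor the 10 highest sequences thus set the direction there. A biological difference between the kinds of cell stays open and untested.

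The rRNA share had a WGA to input log2 ratio of 0.0688 in neutrophils against -0.03 and -0.25 in HOXB8 and differentiated HOXB8 cells, and this difference was not tested. As shares of all reads of the library the rRNA ratios were 0.10, 1.17 and 0.21, so the difference in direction did not hold. The tRNA share had 1.38 in neutrophils against -2.31 and -0.44, and this difference was not tested. As shares of all reads the tRNA ratios were 1.41, -1.11 and 0.02. As shares of distinct sequences they were -0.67, -0.22 and -0.75, so the difference in direction did not hold there. In the same order of cells they were 1.83, -0.98 and -0.16 without each library's 10 highest sequences. At 20 or more bases they were 0.83, -0.25 and -0.55, and at or above the median mean 1.42, -2.50 and -0.45.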

How the results depend on the processing

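The fits without the 5 rRNA-sequence genes, the edgeR test on recovered reads, the read length limit of 20 bases and the shares of all reads were chosen only after the results were seen. The 5 rRNA-sequence genes were called lower in every alternative that tested them, with falls of at least 1.57 on the log2 scale when a library was left out (log2 change -1.57 for CT010467.1). Of 1403 pairs of 111 named genes and alternatives, 1341 kept their direction and side of the threshold, 36 lost a call, 26 gained one and 0 reversed. With 2 libraries per group, and 1 left alone in a group when one is left out and assumed to vary like the other group, counts of weak calls are unstable. The cause of the moves below was not tested unless stated.

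For RNA-seq, 13 genes were called. Without a filter 149 were called, with the stricter filter 7, with limma on TPM 7 and on FPKM 7, and without the 5 genes 3. Leaving out 1 library gave between 9 and 74 calls: 74 without mock replicate 1, 59 without exRNaseA replicate 1 and 29 without exRNaseA replicate 2. The share of genes with an interval within ±1 was 50.1% without a filter, 99.9% with the stricter filter, which keeps abundant genes, and between 76.0% and 76.3% with a library left out. The distance ratio was 1.05 on TPM and the correlation with length 0.16 with the stricter filter. Lists called were 0 with an estimated correlation, 0 with fry, 0 with total count scaling and between 0 and 0 with a library left out.

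With the replicate block, 55 genes were called (29 lower, 26 higher), the share within ±1 was 85.7% and 0 lists were called. Same-numbered libraries had a correlation of deviations of -0.03, and the labels give no pairing behind the number. The same fit called 35 genes by replicate number. The block ended the 3 list calls and no gene call.

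For the genome class, log2 ratios follow in the order HOXB8 WGA, differentiated WGA, neutrophil WGA, HOXB8 biotin and differentiated biotin, each over input. At or above the median mean they were 2.34, 3.34, -1.001, 2.76 and 3.07. Without the 10 highest sequences they were -0.16, 1.63, 0.77, -0.28 and 0.85. As shares of distinct sequences they were -0.19, 0.77, 0.42, -0.45 and -0.22. Among sequences of 20 or more bases they were -0.76, 1.09, 2.07, -1.31 and -0.64. As shares of all reads of the library, which differ because the table holds unequal parts of the libraries, they were 3.46, 3.76, -0.39, 3.88 and 3.39. As shares of all reads, differentiated over undifferentiated input, biotin and WGA were -0.27, -0.76 and 0.0329, and neutrophil over differentiated input and WGA -0.29 and -4.44. For PNGase over biotin, the values without the 10 highest, as distinct sequences and at 20 or more bases were 0.0264, -0.0026 and -0.0324, and for differentiated over undifferentiated input -0.67, -0.17 and -1.28. In the order median mean, 10 highest, distinct and 20 bases, differentiated over undifferentiated biotin was -0.79, 0.46, 0.0611 and -0.61, and WGA -0.11, 1.13, 0.78 and 0.57. Neutrophil over differentiated input was -0.58, -0.40, 0.22 and -1.57, and WGA -4.93, -1.26, -0.12 and -0.59. In the order median mean, 10 highest, distinct, 20 bases and all reads, the sign turned in 1, 5, 8, 6 and 2 of 11 comparisons for genome, 0, 6, 3, 2 and 1 for ncRNA, 0, 6, 8, 4 and 4 for rRNA, 0, 0, 6, 0 and 0 for snoRNA, and 0, 2, 4, 2 and 1 for tRNA. Classes on the same side in all 3 kinds of cell were 6, and 5 as shares of all reads. Of the class values, 255 moved beyond their counting interval and 20 did not.

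For sequences 4-fold or more higher and lower, 10 RPM added gave 952 and 940 for HOXB8 biotin, 1536 and 886 for HOXB8 WGA, 702 and 1064 for differentiated biotin, 655 and 1123 for differentiated WGA, 690 and 1056 after PNGase and 346 and 803 for neutrophil WGA. With 0.1 RPM added 6820 were lower in differentiated WGA and 5863 in neutrophil WGA. Median-ratio scaling gave 3390 higher in differentiated biotin and 2875 after PNGase. At or above the median mean, which tests fewer sequences, 3514, 3862, 3010, 2244, 2984 and 743 were higher in HOXB8 biotin, HOXB8 WGA, differentiated biotin, differentiated WGA, PNGase and neutrophil WGA. At 20 or more bases, HOXB8 biotin had 3550 higher and 1717 lower and HOXB8 WGA 3860 and 1745, and 2088, 2448 and 2079 were lower in differentiated biotin, differentiated WGA and PNGase.

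The limma count over the 3 kinds of cell was 419, 9 of them higher. It was 174 with 10 RPM added (2 higher), 463 with 0.1 RPM added (1 higher), 698 with median-ratio scaling (1 higher), 404 at or above the median mean (9 higher), 194 without kind of cell as block (0 higher) and 27 with edgeR on reads (0 higher). Leaving out 1 kind of cell gave between 23 and 1871: 23 without differentiated HOXB8 (0 higher), 147 without HOXB8 (0 higher) and 1871 without neutrophils (769 higher and 1102 lower). No paired analysis by replicate number was possible for small RNA because each group had 1 library.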

Other observations

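The test of small non-polyadenylated RNA genes was chosen only after the result was seen. Sequences shared by the HOXB8 WGA libraries were partly seen in neutrophils. In both HOXB8 kinds 1887 sequences were 4-fold or more higher after WGA, 1333 of them rRNA and 202 of the genome class. The table's 18385 sequences held 9798 of rRNA and 3226 of the genome class. Of the 1887, 1424 stood at 1 RPM or less in both neutrophil libraries. The 1887 made up 31.6% of the neutrophil WGA value and 3.89% of the neutrophil input value. Most of the former was the spacer fragment TCTTAGATCGATGTGGTGCTC, with 20.4%, and CTCTTAGATCGATGTGGTGCTC, with 8.17%. In neutrophils 73 of the 1887 sequences were 4-fold or more higher after WGA and 130 were 4-fold or more lower. Among all 18385 sequences, 1740 were 4-fold or more higher there and 1914 were 4-fold or more lower, so both shares were smaller among the 1887. The 1424 at 1 RPM or less in both neutrophil libraries could not reach 4-fold with 1 RPM added. Of the value in the table, miRNA sequences held 3.46% of the HOXB8 input and 2.60% after WGA, 1.83% and 1.54% in differentiated cells, and 3.08% and 1.25% in neutrophils. Summed in RPM, which scales to all reads, the table's miRNA class was higher after WGA in HOXB8 (13589 and 23564) and differentiated cells (12872 and 14900). It was lower in neutrophils (27187 and 11276). These values cover only miRNA sequences left in a table titled non-miRNA. snRNA held 0.615% and 0.239%, 0.936% and 0.245%, and 1.31% and 0.608% in the same libraries.

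The 5 rRNA-sequence genes fell in the exRNaseA libraries. If less RNA without a poly(A) tail had been carried through selection, other such RNA would have fallen too. The summed counts of 8 genes of 7SK, 7SL, RNase P, RNase MRP and snRNA were 135 in the mock and 131 in the exRNaseA libraries, a log2 ratio of -0.0293 (exact interval -0.39 to 0.33), and the 23 tested Hist genes had a median of -0.05094 (-0.21 to 0.07), both above the smallest fall of the 5, -1.67. Cutting by length in the lysate predicted a negative correlation of log2 change with length, and it was 0.0644. The counts of the 8 genes were few. Whether reads of these genes and of the Hist genes came from RNA without a poly(A) tail cannot be read from the counts. Less carry-through is therefore not excluded. An action of RNase A on rRNA and a library difference specific to rRNA also remain open and were not tested.

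The 6 input and WGA libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 419 calls and the highest of the others 3140, and 5 of the 10 splits, counting the real one, gave at least 419. Kind of cell was a term in the fit, so a split that keeps both libraries of 2 kinds together rests on the WGA and input difference of the remaining kind alone. Such splits gave 3140 calls for the HOXB8 pair, 1468 for the differentiated pair and 0 for the neutrophil pair. The 3 other splits that part every pair, as the real one does, gave 0 calls each.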
